A study of Mus musculus with 12 samples.

How the data were processed

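Poly-A RNA of 12 sorted samples of mouse OT-II CD4 T cells was measured by RNA sequencing, 3 samples in each of the groups Th1 WT, Th1 KO, Th17 WT and Th17 KO. Per the labels' protocols, full-length cDNA was made with a template-switching kit that does not mark strand, fragmented by tagmentation and sequenced as read pairs. Per the submitters' processing notes, TopHat2, Bowtie2 and featureCounts were used with GRCm38 (mm10). Their versions, the strand setting, the treatment of reads that match several places and the annotation release were not given in the sources used here. The deposited values are whole-number read counts per Ensembl gene ID with no normalisation, per the files' values, which summed to a different total in each sample.

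The tables held 39179 gene IDs, of which 37607 (96.0%) were named and placed with a GENCODE annotation of GRCm38. The other 1572 were kept under their ID. Genes with near-identical copies (the Klrc, Klra, Gbp, Gzm and Tnfrsf22, Tnfrsf23 and Tnfrsf26 families) and genes that overlap on opposite strands (Echs1 with Paox, Mtg1 with Sprn) are uncertain, because shared reads could have been split or dropped in counting and strands were not told apart. Labels gave no replicate numbers, so replicates are numbered in the order of deposit and the numbers are only names.

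Counts were normalised by TMM in edgeR 4.0.16 and filtered with filterByExpr over the 4 groups, which left 12189 genes. Groups were compared with edgeR's quasi-likelihood F-test with robust dispersion on all 12 samples and Benjamini-Hochberg adjustment within each of 6 comparisons, with 0.05 as the threshold. The comparisons were KO with WT in Th1, KO with WT in Th17, Th17 with Th1 in WT, Th17 with Th1 in KO, the genotype difference averaged over both cell types, and the difference between the genotype differences (interaction). Positive values mean higher in KO, or higher in Th17. Standard errors (SE) of log2 fold changes were the absolute fold change over the root of F. CPM values are TMM-normalised and given as mean ± SD. Lists of genes, 32 in all, covered lineages, receptors, pathways and markers of other cells. Those with at least 5 tested members, 26 lists, were tested with camera in limma 3.58.1 on log CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the lists of a comparison. Under an estimated correlation 18 of the 74 list calls remained. Ranges of a gene's adjusted p over all alternatives include the block by library code. The range beside a list's adjusted p runs over its camera alternatives. Fry tests a list against no change and not against other genes, so its adjusted p is kept apart and named where a camera call was lost with it. Where leaving out a library moved a list's count of members by over 1.5 times, the count without it is given. So it is for other alternatives in the genotype comparisons and the interaction where at least 2 members had passed, except those that test other numbers of genes (thinned, no filter) and the block. Groups of 3 against 3 cannot give an exact permutation p under 0.1. The 6 comparisons, the tests, the lists, the naming rule and the alternatives other than those for the 3 shallow libraries were set before the data were examined.

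Genes were named by rule. In each comparison of 2 groups these were Klrk1, Hcst, Tyrobp and Thy1; the lineage genes Tbx21, Ifng, Il17a and Il17f; and the 8 highest and 8 lowest log2 fold changes past the threshold with a mean of at least 5 CPM in the higher group and CPM ranges that did not overlap, which chance gives for 10% of genes. Predicted names, Rik clones, pseudogenes and receptor or immunoglobulin segments were left out. Some genes that met the rule are not reported here. Up to 4 members of smallest p past the threshold, or the 1 of smallest p where none passed, served as examples of a list. For the average and the interaction only the highest and lowest genes were named, without the range criterion. Echs1, Tspan32, Tnfrsf23 and Tnfrsf26 in the average comparison, and the genes of a chromosome 7 window, were chosen after their values were seen.

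Alternatives were RLE size factors, DESeq2 1.42.0, no filter on low counts, limma-voom with sample weights, libraries thinned to the smallest total, only the groups compared in the fit, a block by library code, each sample left out in turn and, for lists, an estimated correlation and fry. Added after seeing the library totals were a fit without the 3 shallow libraries, which leaves 1 Th17 WT library whose spread is assumed to be like that of the other groups, a term for them, and counts without their dominant ID. A ratio against a group with 0 counts was computed against a floor of 3 counts over the group and is a lower bound; with 1 to 3 counts the ratio has a 95% counting interval. The code ran in R 4.3.3 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

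Each test was run on simulated counts with 200 changed genes. At 1.5, 2 and 3-fold it recovered 64.7%, 81.5% and 95.3% in the Th1 genotype comparison (12040 genes, 6.51% of calls false), 60.6%, 74.6% and 88.2% in the Th17 one (11999 genes, 6.37%), and 30.8%, 72.6% and 80.3% in the interaction (12047 genes, 4.69%). Camera called 10 of 10 shifted lists in each comparison and 0 of 40 unchanged, except 1 in Th17 with Th1 in WT. With an estimated correlation it called 8 of 10 shifted lists for Th17 genotypes, 9 for the interaction, 10 elsewhere and 0 of 40 unchanged. These shares may not hold for correlated genes (18 of 74 real calls kept).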

Results

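Gene expression was measured by RNA sequencing in mouse CD4 T cells carrying the OT-II transgenic T cell receptor, which recognises an ovalbumin peptide. Wild-type cells (WT) and cells without NKG2D (KO), the activating receptor encoded by Klrk1, were grown together with antigen-presenting cells, the peptide and an antibody to CD28. Th1 cultures received the cytokines IL-12 and IL-2 together with an IL-4 block. Th17 cultures received IL-23, IL-6 and IL-1b with blocks of IL-4 and IFNg, and IL-12 from the second stimulation on. Polarization was started on day 0 and repeated on day 5, and the cells were sorted on day 8. The congenic Thy1 allele told the genotypes apart, and WT cells were additionally gated as NKG2D positive. Each of the 4 groups (Th1 WT, Th1 KO, Th17 WT and Th17 KO) held 3 samples, 12 in all. Genotype, the NKG2D gate and the Thy1 allele differ together in every comparison of KO with WT. The labels do not say which samples shared a culture or came from separate animals, so p-values measure only the spread between these samples, which may be technical.

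The 6 Th1 libraries held 9108203 to 12688637 gene counts. Th17 WT 1, Th17 KO 1 and Th17 KO 3 held 10405299, 11587560 and 10728293 counts, while Th17 WT 2, Th17 WT 3 and Th17 KO 2 held 2731909, 1647232 and 1722228. In these 3 shallow libraries a single ID, ENSMUSG00000045999, which has no name in the annotation used, took 18.3%, 48.1% and 51.0% of the counts, against at most 0.00831% in the other 9. Between 12430 and 17378 genes had at least 1 count. A count of 0 allows up to 3 counts, equal to 0.236 to 1.82 CPM (counts scaled to library size) across the libraries, and such floors cover counting error only. Of the counts other than that ID, mitochondrial genes took 14.2% to 14.8% in Th1 WT, 14.6% to 15.1% in Th1 KO, 16.9% to 18.6% in Th17 WT and 19% to 20.8% in Th17 KO. The first principal component of the log CPM separated Th1 from Th17 libraries and held 55.7% of the variance, followed by 15.5% and 12.3%.

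Klrk1 (ENSMUSG00000030149, chromosome 6, 129610323 to 129623864 on GRCm38) was low in every KO library. Its normalised level was 161, 158 and 128 CPM in the Th1 WT libraries and 5.58, 5.63 and 3.31 CPM in the Th1 KO libraries. In Th17 cells it was 130, 141 and 133 CPM in WT and 3.35, 2.10 and 1.60 CPM in KO. The difference was 30.7-fold in Th1 (log2 fold change -4.94, SE 0.16, adjusted p = 1.19e-09) and 53.7-fold in Th17 (log2 fold change -5.75, SE 0.22, adjusted p = 6.24e-09). Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579), whose protein allele marked the genotypes, gave -0.12 ± 0.12 (log2 fold change ± SE, adjusted p = 0.716) in Th1 and -0.35 ± 0.13 (adjusted p = 0.169) in Th17. The Th17 value passed without Th17 KO 2 (adjusted p = 6.69e-04, range over all alternatives 1.35e-04 to 0.423). Hcst (ENSMUSG00000064109, chromosome 7, 30417712 to 30419854), the adaptor through which NKG2D signals, averaged 14.3 ± 0.399 CPM in Th1 WT (SD, n = 3), 13.6 ± 0.399 in Th1 KO, 11.4 ± 0.0245 in Th17 WT and 8.01 ± 0.479 in Th17 KO. It was not past the threshold in Th1 (adjusted p = 0.829). In Th17 it was lower in KO (log2 fold change -0.55, SE 0.15, adjusted p = 0.0326), a call lost in several alternatives (adjusted p = 0.181, 0.0738, 0.236, 0.0777 and 0.05 without Th17 KO 1, KO 3, WT 1, WT 2 and WT 3 and 0.0505 and 0.0507 without Th1 KO 2 and WT 2, range over all alternatives 0.0302 to 0.581). Tyrobp, the other adaptor of the receptor, had 0 to 3 counts per library and was not tested. Of the NKG2D ligand genes listed, only Ulbp1 had enough counts for a test, with -0.05 ± 0.11 (adjusted p = 0.889) in Th1 and 0.45 ± 0.17 (adjusted p = 0.137) in Th17. The Th17 value passed without Th17 WT 3 (adjusted p = 0.0382, range over all alternatives 0.0337 to 0.908).

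Whether loss of NKG2D goes with a different transcriptome in Th1 cells was addressed by comparing Th1 KO with Th1 WT. In the KO cells 10 of 24 genes of the interferon response were lower, a list call lost with an estimated correlation. Gbp2, an interferon-induced GTPase, was 834 ± 60.4 CPM in WT and 407 ± 31 in KO (SD, n = 3 per group), a difference of log2 fold change -1.03, SE 0.07, adjusted p = 6.02e-11. Tnfrsf26 (ENSMUSG00000045362, chromosome 7, 143607659 to 143628722), a decoy receptor of the TNF family, fell from 38 ± 1.41 to 0.132 ± 0.0341 CPM (log2 fold change -8.02, SE 0.21, adjusted p = 5.66e-20). Of 12189 genes tested, 562 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 206 higher and 356 lower in KO, and 55 of the higher and 33 of the lower genes differed by more than 2-fold. Without Th1 WT 2, KO 1 or KO 2 the count was 260, 343 or 293.

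Besides Tnfrsf26 and Klrk1, genes far below WT in Th1 KO included Tspan32 (-4.32 ± 0.26), Tnfrsf23 (-4.23 ± 0.35), Serpinb5 (-2.16 ± 0.25), Cmss1 (-2.04 ± 0.27) and Sla2 (-1.92 ± 0.10), as log2 fold change ± SE with n = 3 per group. Tspan32 encodes a tetraspanin of blood cells, Sla2 an adaptor that dampens T cell receptor signalling. Tnfrsf23 and Tnfrsf26 belong to 1 gene cluster, so shared reads could affect their values. The cluster lies past a chromosome 7 window of gathered genotype calls (see Other observations). The genes furthest above WT included Trp73 (1.77 ± 0.20), Cd200r1 (1.66 ± 0.24), Lrrc32 (1.60 ± 0.19), Tmem176b (1.22 ± 0.14) and Tubb6 (1.18 ± 0.12). Trp73 encodes a p53 family transcription factor, Cd200r1 an inhibitory receptor and Lrrc32 (GARP) a surface anchor of latent TGF-beta.

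The interferon response list had 10 of its 24 tested members lower in Th1 KO and none higher (15 lower adjusted over the list alone, camera adjusted p = 5.44e-16, adjusted p = 0.091 with an estimated correlation, range 1.08e-19 to 0.091). Besides Gbp2, these included Iigp1 (-1.45 ± 0.10) and Zbp1 (-0.74 ± 0.07). The Th1 programme list had 6 of 20 lower and none higher (7 lower adjusted over the list alone, camera adjusted p = 8.02e-05, adjusted p = 0.142 with an estimated correlation, range 7.92e-06 to 0.142). Th1 programme counts were 2 lower without Th1 KO 2 and 3 lower without Th1 WT 2 or WT 3. Examples were Hlx (-0.62 ± 0.09) and Il18r1 (-0.37 ± 0.08). Hlx encodes a homeobox factor of Th1 cells and Il18r1 a receptor subunit for IL-18. The Il18r1 call was lost with an adjusted p of 0.0602 without Th1 KO 2 (range over all alternatives 1.90e-06 to 0.0602), and the Hlx call with thinned libraries (adjusted p = 0.108, range 2.97e-08 to 0.108). Ifng (-0.21 ± 0.20, adjusted p = 0.703) and Tbx21, which encodes T-bet (-0.42 ± 0.18, adjusted p = 0.299), did not pass. The ranges over all alternatives were 0.00934 to 0.997 for Ifng and 2.85e-06 to 0.579 for Tbx21, both passing with the block by library code (the lower ends). Tbx21 also passed in a fit of the 2 groups alone (adjusted p = 0.0281). The cell cycle list had 5 of 25 lower, such as Cenpf (-0.39 ± 0.07), and none higher (12 lower adjusted over the list alone, camera adjusted p = 1.59e-04, adjusted p = 0.145 with an estimated correlation, range 2.13e-05 to 0.145). Cell cycle counts were 1 lower without Th1 WT 2, KO 1 or KO 2, 3 lower without Th1 WT 3 or KO 3 or with DESeq2, 9 lower without the shallow libraries, 10 lower with the 2 groups alone or with a term for the shallow libraries and 12 lower with limma-voom. The costimulation and inhibitory receptor list had 1 of 17 higher, Cd200r1, and 4 lower (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.0193, adjusted p = 0.142 with an estimated correlation, range 0.00819 to 0.142). Costimulation counts were 2 lower without Th1 WT 1, WT 2, KO 1, KO 3, Th17 WT 3 or KO 2, with DESeq2, with the 2 groups alone or without the shallow libraries. Examples were Entpd1 (-0.78 ± 0.08) and Cd28 (-0.31 ± 0.06). The unfolded protein response list shifted upward as a whole, with a mean log2 fold change of 0.14 over 19 members, of which 0 passed singly in edgeR's test (0 adjusted over the list alone, camera adjusted p = 9.68e-04, adjusted p = 0.142 with an estimated correlation, range 1.61e-04 to 0.142). Unfolded protein counts were 1 higher without Th1 KO 3. Of these members 7 had an unadjusted p under 0.05, and 0 passed with DESeq2 and 4 with limma-voom.

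Genes of the Th17 programme were divided in Th1 KO, with 4 of 21 higher and 1 lower (5 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.0351, adjusted p = 0.437 with an estimated correlation, range 0.00938 to 0.437, fry adjusted p = 0.342). Th17 programme counts were 2 higher without Th1 WT 1, WT 2 or KO 2 and 0 lower without any 1 Th1 library or Th17 WT 3. The list call was lost in single left-out libraries (adjusted p = 0.0685 without Th17 KO 2 and 0.135 without Th1 KO 2). The higher members included Tmem176b (1.22 ± 0.14) and Tmem176a (1.09 ± 0.15). With thinned libraries Tmem176a had a log2 fold change of 0.64 and did not pass (adjusted p = 0.34, range over all alternatives 5.28e-12 to 0.34). Il17a had 0 counts in all 6 Th1 libraries, and Il17f had 1 count in WT and 2 in KO. Of 19 cytokine genes only Tnfsf8 (0.94 ± 0.18), which encodes CD30 ligand, passed, and it was higher (4 higher and 0 lower adjusted over the list alone, camera adjusted p = 0.0381, adjusted p = 0.142 with an estimated correlation, range 0.022 to 0.147). Cytokine counts were 2 higher without Th1 WT 1, KO 3, Th17 KO 1 or KO 3 and 3 higher without Th17 WT 1. That list lost its call in single left-out libraries (adjusted p = 0.0537, 0.0699 and 0.0568 without Th17 KO 1, KO 2 and WT 3 and 0.0571, 0.0597 and 0.0873 without Th1 KO 2, WT 2 and WT 3).

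Early activation genes had 3 of 19 members lower and 0 higher in Th1 KO (3 lower adjusted over the list alone, camera adjusted p = 0.0359, adjusted p = 0.437 with an estimated correlation, range 0.024 to 0.437, fry adjusted p = 0.308). Early activation counts were 1 lower without Th1 WT 1 or without the shallow libraries. For early activation the adjusted p was 0.0685 without Th17 KO 2 and 0.0571 and 0.0924 without Th1 KO 2 and WT 3. The lower members included Tnfaip3 (-0.46 ± 0.07), a brake on NF-kB signalling. Ribosomal protein genes were shifted upward by a mean log2 fold change of 0.05, with 0 of 26 past the threshold in edgeR's test, 1 at an unadjusted p under 0.05 and 0 with DESeq2 or limma-voom (0 adjusted over the list alone, camera adjusted p = 0.0268, adjusted p = 0.7 with an estimated correlation, range 1.61e-04 to 0.7, fry adjusted p = 0.589). For ribosomal proteins the adjusted p was 0.258, 0.102 and 0.24 without Th1 KO 1, KO 2 and WT 3. The naive and memory list had 6 of 15 lower (2 higher and 7 lower adjusted over the list alone), with Foxp1 (-0.55 ± 0.08) and Foxo1 (-0.43 ± 0.07), but did not pass as a list (camera adjusted p = 0.05 after rounding, 3 lower without Th1 KO 2). Other NK receptors had 3 of 13 lower (1 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.05 after rounding, 0 lower without Th1 KO 2 or with DESeq2 and 1 lower without Th1 WT 2, WT 3 or KO 1). Cytotoxic effectors had 1 of 16 lower (3 lower adjusted over the list alone, camera adjusted p = 0.804, direction down with a mean log2 fold change of 0.06, 0 lower without Th1 WT 2, WT 3, KO 1, KO 2 or KO 3 and 3 lower without Th17 WT 1, WT 2, KO 1 or KO 3).

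In Th17 cells, KO was lower than WT for natural killer cell receptors, cytotoxic effectors and genes of the Th1 programme, and higher for Il17f, a cytokine gene of Th17 cells. Klrd1 (ENSMUSG00000030165, chromosome 6, 129591782 to 129598775), which encodes CD94, was 89.4 ± 7.85 CPM in WT and 26.8 ± 1.53 in KO (SD, n = 3 per group), a difference of log2 fold change -1.77, SE 0.09, adjusted p = 8.69e-13. Ifng, the signature Th1 cytokine, averaged 195 ± 32.8 CPM in WT and 55 ± 14.5 in KO (log2 fold change -1.66, SE 0.24, adjusted p = 0.00566). Il17f went the other way, from 2.38 ± 1.34 to 11.6 ± 2.94 CPM (log2 fold change 1.98, SE 0.27, adjusted p = 2.42e-05). Of 12189 genes, 711 passed in edgeR's quasi-likelihood test, 221 higher and 490 lower in KO, of which 49 and 109 differed by more than 2-fold. Without Th17 WT 2, KO 1 or KO 3 the count was 411, 453 or 458. Mitochondrial genes took a larger share of the counts other than the dominant ID in each Th17 KO library (20.2%, 19% and 20.8%) than in any Th17 WT library (16.9%, 18.6% and 17.6%), a separation that chance gives in 10% of cases, while the list of mitochondrially encoded genes did not pass (camera adjusted p = 0.562). A fit without the 3 shallow libraries, chosen after seeing the data, left 1 Th17 WT and 2 Th17 KO libraries, so the spread of the lone WT library was assumed to be like that of the other groups. There 319 genes passed (59 higher and 260 lower), 281 of them shared with the 711, and Ifng had a log2 fold change of -1.47 but did not pass (adjusted p = 0.116, range over all alternatives 1.33e-19 to 0.116).

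**Figure D1:**
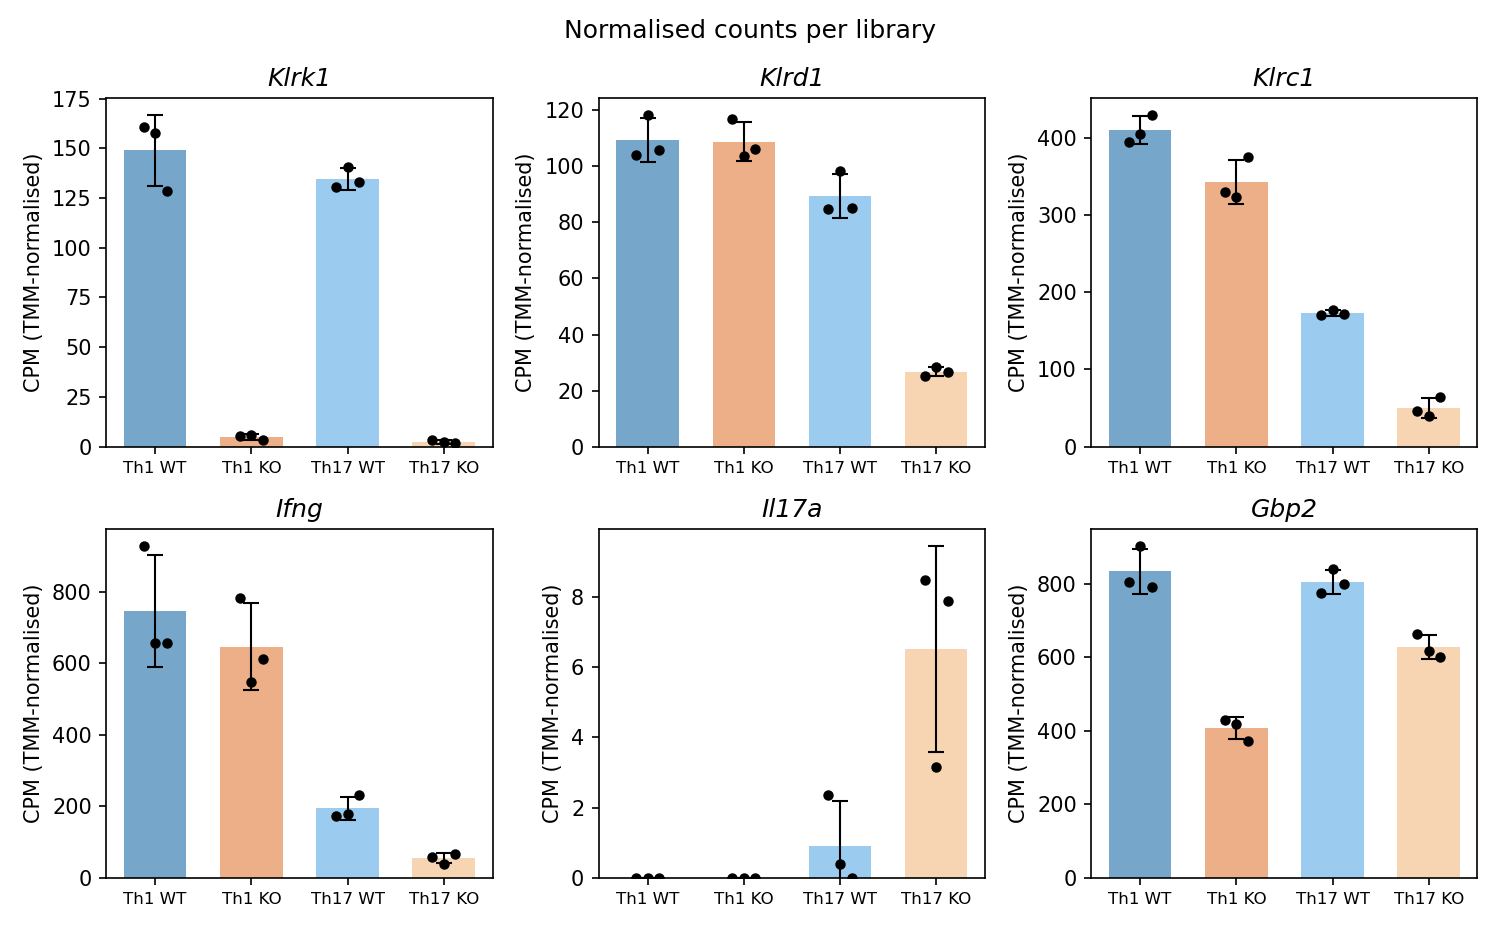
TMM-normalised CPM (vertical axes, from 0) of 6 genes in the 4 groups. Points are the 3 libraries of each group, bars the mean and whiskers the SD. Klrk1 lies at or below 5.63 CPM in all 6 KO libraries, and Klrd1 averages 26.8 CPM in Th17 KO against 89.4 in Th17 WT, while Il17a has 0 counts in all 6 Th1 libraries.

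The other NK receptor list had 8 of 13 members lower in Th17 KO and none higher (9 lower adjusted over the list alone, camera adjusted p = 1.07e-10, adjusted p = 0.0104 with an estimated correlation, range 1.03e-10 to 0.0104). NK receptor counts were 5 lower with the 2 groups alone. Examples were Klri2 (-2.00 ± 0.23), Klrc2 (-1.94 ± 0.14) and Klrc1 (-1.69 ± 0.12) as log2 fold change ± SE. Klrc1 (ENSMUSG00000030167, chromosome 6, 129666015 to 129678973) encodes NKG2A, the partner of CD94, and fell from 173 ± 3.5 to 50.3 ± 12.6 CPM (SD, n = 3). Klrc1 and Klrc2 are similar in sequence, so their separate values are uncertain where reads could be shared. Klrk1 and its chromosome 6 neighbours, which include these receptors, had 11 of 22 lower, Klrk1 among them, and none higher (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 1.15e-08, adjusted p = 0.0104 with an estimated correlation, range 8.09e-10 to 0.0104). Neighbour counts were 7 lower without Th17 WT 1 or with the 2 groups alone. Markers of NK and innate lymphoid cells had too few tested members for a list test, and Kit (-1.92 ± 0.21) and Klre1 (-2.55 ± 0.44) were lower among the 3 tested (2 lower adjusted over the list alone). Ncr1 had 0 counts in all libraries, Tyrobp 0 in each Th17 WT library and Fcer1g 1 to 3.

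Cytotoxic effectors had 6 of 16 lower and none higher (9 lower adjusted over the list alone, camera adjusted p = 1.61e-07, adjusted p = 0.0104 with an estimated correlation, range 3.84e-08 to 0.0104). Cytotoxic counts were 3 lower without the shallow libraries. Fasl, the ligand of the death receptor Fas, fell by 1.78 on the log2 scale (SE 0.25, adjusted p = 3.89e-04), and by 1.11 without Th17 WT 1. Tnfsf10, which encodes TRAIL, gave -0.99 ± 0.19. Nkg7, of cytotoxic granules, gave -1.57 ± 0.23 (adjusted p = 0.00346), and -1.44 (adjusted p = 0.0946) without the 3 shallow libraries, with 1 Th17 WT library left (range over all alternatives 3.78e-15 to 0.0946). The Th1 programme list had 10 of 20 lower and none higher (12 lower adjusted over the list alone, camera adjusted p = 3.06e-11, adjusted p = 0.0104 with an estimated correlation, range 8.11e-12 to 0.0104). Th1 programme counts were 6 lower without the shallow libraries. Members past the threshold included Hlx (-1.14 ± 0.14), Il18r1 (-0.82 ± 0.09) and Ifngr1 (-0.62 ± 0.07). Tbx21 (-0.62 ± 0.22, adjusted p = 0.186) did not pass, but did with DESeq2 and the block (adjusted p = 0.0195 and 6.05e-08, at most 0.503 over all alternatives). The costimulation and inhibitory receptor list had 3 of 17 lower and none higher (4 lower adjusted over the list alone, camera adjusted p = 0.0077, adjusted p = 0.0622 with an estimated correlation, range 0.00371 to 0.0878), namely Lag3 (-1.26 ± 0.13), Cd96 (-1.18 ± 0.21) and Entpd1 (-1.14 ± 0.11).

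In the Th17 programme 4 of 21 members were higher and 1 lower in Th17 KO (5 higher and 1 lower adjusted over the list alone), and the list did not pass (camera adjusted p = 0.154, 2 higher with DESeq2, 0 lower without Th17 WT 1 or KO 3 and 2 lower without Th17 KO 1). Il17a averaged 0.923 ± 1.27 CPM in WT and 6.51 ± 2.92 in KO (SD, n = 3 per group), a difference of log2 fold change 2.12, SE 0.41, adjusted p = 0.00504. Without Th17 WT 1 the log2 fold change of Il17a was 4.70, and with DESeq2 it did not pass (adjusted p = 0.519, range over all alternatives 7.43e-08 to 0.519). Il23r, the receptor subunit for IL-23, was higher (log2 fold change 0.75, SE 0.12, adjusted p = 1.45e-04). Il10, which many helper subsets make, was lower (log2 fold change -1.60, SE 0.38, adjusted p = 0.011), but had an adjusted p of 0.0727 without Th17 KO 3 and 0.762 without Th17 WT 1 (range over all alternatives 0.00265 to 0.79, log2 fold change -0.62 without Th17 WT 1). Il10 did not pass with limma-voom (adjusted p = 0.23) or thinned libraries (adjusted p = 0.79) either. Of the 19 cytokine genes 4 were higher and 2 lower (4 higher and 4 lower adjusted over the list alone), Tnfsf8 (0.90 ± 0.12) being higher as in Th1, and the list did not pass (camera adjusted p = 0.176, 1 lower without Th17 WT 1 or KO 3, with limma-voom, with the 2 groups alone or without the shallow libraries).

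Beyond the listed genes, Tnfrsf26 (-5.86 ± 0.22), Zfp941 (-3.43 ± 0.33), Camk2b (-2.68 ± 0.41), Sprn (-2.17 ± 0.41), Ncald (-2.07 ± 0.31) and Sla2 (-2.03 ± 0.14) were among the furthest below WT in Th17 KO. Pparg, a nuclear receptor, was above WT (1.52 ± 0.29), with a log2 fold change of 2.87 without Th17 WT 1. Dab2, an endocytic adaptor, gave 1.71 ± 0.29 (adjusted p = 4.87e-04), with an adjusted p of 0.059 without Th17 WT 1 (range over all alternatives 6.03e-08 to 0.059). The cell cycle list had 7 of 25 lower and none higher (14 lower adjusted over the list alone, camera adjusted p = 3.64e-06, adjusted p = 0.0666 with an estimated correlation, range 2.28e-06 to 0.0666), with Cenpf at -0.48 ± 0.08. Cell cycle counts were 1 lower without Th17 WT 3 or KO 1 or with the 2 groups alone, 3 lower with limma-voom or without the shallow libraries and 4 lower without Th1 KO 2, Th17 WT 2 or KO 3. The T cell receptor complex list had 5 of 14 lower (7 lower adjusted over the list alone, camera adjusted p = 1.53e-04, adjusted p = 0.0666 with an estimated correlation, range 2.47e-05 to 0.0666), with Lat at -0.39 ± 0.08. Receptor complex counts were 1 lower without Th1 WT 2, Th17 WT 2, WT 3 or KO 1, with the 2 groups alone or without the shallow libraries, 2 lower without Th17 KO 3 and 3 lower without Th1 KO 2 or with a term for the shallow libraries. B cell and antigen presentation markers had 1 of 6 higher, Cd74 (0.49 ± 0.12), and none lower (1 higher adjusted over the list alone). Their mean log2 fold change was 0.40, and the list did not pass (camera adjusted p = 0.0598, fry adjusted p = 0.00583, 0 higher without Th17 KO 3 and 2 higher without Th17 WT 1 or KO 1). Cholesterol synthesis genes had 4 of 20 lower (6 lower adjusted over the list alone, camera adjusted p = 0.0063, adjusted p = 0.335 with an estimated correlation, range 0.00208 to 0.335). Cholesterol synthesis counts were 2 lower without Th17 WT 3 or KO 3, with limma-voom, with the 2 groups alone or without the shallow libraries. Examples were Srebf2 (-0.37 ± 0.07) and Lss (-0.38 ± 0.09). Ribosomal protein genes were shifted upward, with 1 of 26 higher (5 higher adjusted over the list alone, camera adjusted p = 1.95e-05, adjusted p = 0.422 with an estimated correlation, range 1.60e-06 to 0.422, fry adjusted p = 0.0697). Ribosomal counts were 0 higher without Th1 WT 1, WT 2, KO 1, KO 2, Th17 WT 2, KO 1, KO 2 or KO 3 and 8 higher without Th17 WT 1. The interferon response list had 4 of 24 lower (7 lower adjusted over the list alone) and did not pass (camera adjusted p = 0.0592, 1 lower without the shallow libraries and 2 lower with limma-voom or with the 2 groups alone), with Gbp2 (-0.36 ± 0.07) and Usp18 (-1.60 ± 0.30). Without the 3 shallow libraries, which leaves 1 Th17 WT library, the log2 fold changes of Gbp2, Usp18, Lat and Lss were -0.30, -1.47, -0.28 and -0.32, and these genes did not pass (adjusted p = 0.117, 0.16, 0.0748 and 0.0688, ranges over all alternatives 4.09e-06 to 0.117, 2.62e-14 to 0.16, 7.87e-05 to 0.0748 and 3.13e-04 to 0.0688). Cd74 did not pass there (log2 fold change 0.42, adjusted p = 0.169), with thinned libraries (adjusted p = 0.09) or without Th17 KO 3 (adjusted p = 0.0733, range over all alternatives 0.00137 to 0.169). Srebf2 did not pass with thinned libraries (adjusted p = 0.0737, range 3.98e-05 to 0.0737), nor Usp18 with limma-voom (adjusted p = 0.0509).

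**Figure D2:**
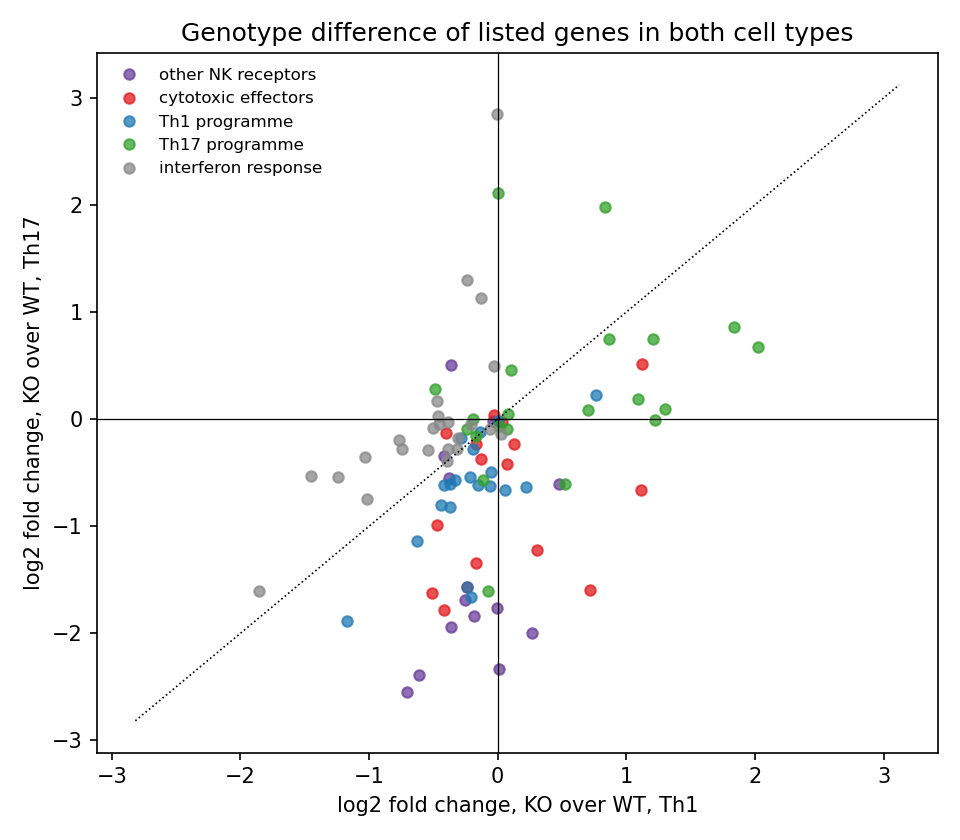
Log2 fold changes of KO over WT in Th1 (horizontal axis) and Th17 (vertical axis) for the tested members of 5 lists, 1 point per gene, coloured by list. The dotted line marks equal change. Klrd1, of the other NK receptors, lies below the line (-0.01 in Th1 and -1.77 in Th17), and Gbp2, of the interferon response, above it (-1.03 and -0.36).

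Whether the genotype difference itself differed between the cell types was tested as an interaction. The lists of other NK receptors, cytotoxic effectors and the Th1 programme shifted toward a more negative difference in Th17 than in Th1, with 4 of 13, 1 of 16 and 1 of 20 members past the threshold singly (all 3 camera calls held with an estimated correlation). Gbp2 of the interferon response had a more positive difference. Klrd1 stood at 109 ± 7.87 CPM in Th1 WT and 109 ± 7.01 in Th1 KO (SD, n = 3), and its genotype difference was lower in Th17 than in Th1 by log2 fold change -1.76, SE 0.11, adjusted p = 3.01e-10. In all, 72 of 12189 genes passed (14 more positive and 58 more negative in Th17), with 38 past the threshold without Th17 KO 3, and 8 of 100 splits of the samples within each cell type, the real one included, gave as many. For the other NK receptors 4 of 13 were more negative and none more positive (1 more positive and 8 more negative adjusted over the list alone, camera adjusted p = 2.06e-10, adjusted p = 0.0117 with an estimated correlation, range 1.61e-10 to 0.0117). The Klrk1 neighbours had 4 of 22 more negative (11 adjusted over the list alone, camera adjusted p = 1.01e-10, adjusted p = 0.00711 with an estimated correlation, range 4.99e-12 to 0.00711). Cytotoxic effectors had 1 of 16 more negative (7 adjusted over the list alone, camera adjusted p = 6.33e-08, adjusted p = 0.00711 with an estimated correlation, range 1.38e-09 to 0.00711). Cytotoxic counts were 0 more negative without Th1 WT 1, WT 2, KO 1, KO 3, Th17 KO 2 or KO 3, 2 more negative without Th1 WT 3 and 3 more negative without Th1 KO 2. The Th1 programme had 1 of 20 (7 adjusted over the list alone, camera adjusted p = 1.22e-07, adjusted p = 0.0395 with an estimated correlation, range 2.28e-08 to 0.0395). Th1 programme counts were 0 more negative without Th1 KO 1 or Th17 KO 3 and 2 more negative without Th17 WT 1 or KO 1. Single genes included Klri2 (-2.26 ± 0.26), Klrc2 (-1.57 ± 0.17), Serpine2 (-1.49 ± 0.14), Tspan32 (2.90 ± 0.33) and Cd274 (0.74 ± 0.13). Serpine2 encodes a protease inhibitor and Cd274 the ligand PD-L1. With libraries thinned to the smallest total, Tspan32, Klri2 and Cd274 did not pass (adjusted p = 0.235, 0.0692 and 0.0593, ranges over all alternatives 1.38e-12 to 0.235, 1.52e-13 to 0.0692 and 2.11e-07 to 0.0593).

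For the interferon response list 4 of 24 members had a more positive difference in Th17 and none a more negative one (5 more positive adjusted over the list alone, camera adjusted p = 3.63e-06, adjusted p = 0.143 with an estimated correlation, range 5.15e-08 to 0.143), Gbp2 with log2 fold change 0.68, SE 0.10, adjusted p = 2.59e-04. Interferon response counts were 1 more positive without Th17 KO 3 and 2 more positive without Th17 WT 1 or without the shallow libraries. Cysltr2, a leukotriene receptor, gave 0.71 ± 0.10. Further lists passed only as shifts, with 0 members past the threshold in edgeR's test. These were the unfolded protein response (2 more negative adjusted over the list alone, camera adjusted p = 0.00146, adjusted p = 0.129 with an estimated correlation, range 3.81e-04 to 0.129) and the T cell receptor complex (0 adjusted over the list alone, camera adjusted p = 0.00144, adjusted p = 0.129 with an estimated correlation, range 1.29e-04 to 0.129), both more negative in Th17. Unfolded protein counts were 1 more negative without Th1 KO 3 or Th17 KO 2. Chemokines and their receptors were also more negative (1 more positive adjusted over the list alone, camera adjusted p = 0.00197, adjusted p = 0.122 with an estimated correlation, range 0.00175 to 0.498). Chemokine counts were 1 more positive without Th17 KO 1 and 1 more negative without Th17 KO 1. For chemokines the adjusted p was 0.0523 without Th17 WT 3. Cholesterol synthesis was more negative (2 adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.376 with an estimated correlation, range 0.00361 to 0.376, fry adjusted p = 0.201). Cholesterol synthesis counts were 1 more negative without Th17 KO 1. For cholesterol synthesis the adjusted p was 0.0729, 0.0726 and 0.0728 without Th17 KO 2, WT 1 and WT 3 and 0.055 and 0.0786 without Th1 KO 1 and WT 1. Ribosomal proteins were more positive (0 adjusted over the list alone, camera adjusted p = 0.0149, adjusted p = 0.764 with an estimated correlation, range 7.14e-04 to 0.897, fry adjusted p = 0.539). For ribosomal proteins the adjusted p was 0.125, 0.193 and 0.0783 without Th17 KO 1, WT 2 and WT 3 and 0.233 and 0.0824 without Th1 KO 3 and WT 1. At an unadjusted p under 0.05 the passing members of these lists numbered 4, 1, 5, 3 and 1 in that order. With DESeq2 0 members passed in each list, and with limma-voom 1 of the unfolded protein response and 0 of the others.

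Averaged over both cell types, KO cells had lower NK receptor, Th1 and cytotoxic genes, lists that fell more in Th17. In Th1 alone the NK receptor and cytotoxic lists did not pass. Tnfrsf26 (log2 fold change -6.94, SE 0.15, adjusted p = 1.24e-21), Klrk1 (-5.34 ± 0.13), Zfp941 (-3.21 ± 0.24), Sla2 (-1.97 ± 0.09) and Usp18 (-1.73 ± 0.18), a negative regulator of interferon signalling, were among the lowest, with n = 6 per genotype. Inhba, which encodes an activin subunit (2.01 ± 0.31), Dab2 (1.90 ± 0.23), Pparg (1.67 ± 0.29) and Mid1 (1.46 ± 0.21) were among the highest. In all 1198 of 12189 genes passed, 389 higher and 809 lower. Between the cell types, 52 higher genes were shared where independent lists would share 3.74, and 150 lower genes where they would share 14.3, while 2 genes passed in opposite directions.

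Of the lists, 13 passed on average. The other NK receptors had 9 of 13 lower (10 lower adjusted over the list alone, camera adjusted p = 2.63e-09, adjusted p = 0.0218 with an estimated correlation, range 8.48e-10 to 0.0218). The Th1 programme had 11 of 20 (1 higher and 13 lower adjusted over the list alone, camera adjusted p = 1.17e-10, adjusted p = 0.0218 with an estimated correlation, range 1.30e-11 to 0.0218). Th1 programme counts were 7 lower without the shallow libraries. Cytotoxic effectors had 6 of 16 (6 lower adjusted over the list alone, camera adjusted p = 3.57e-05, adjusted p = 0.0218 with an estimated correlation, range 1.34e-05 to 0.0218). Costimulation and inhibitory receptors had 5 of 17 lower and 1 higher (1 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.00188, adjusted p = 0.0311 with an estimated correlation, range 8.72e-04 to 0.0311). The Klrk1 neighbours had 11 of 22 lower and 1 higher (1 higher and 12 lower adjusted over the list alone, camera adjusted p = 2.65e-06, adjusted p = 0.0254 with an estimated correlation, range 3.08e-07 to 0.0254). The cell cycle had 15 of 25 lower (18 lower adjusted over the list alone, camera adjusted p = 6.93e-07, adjusted p = 0.0563 with an estimated correlation, range 2.26e-07 to 0.0563). The interferon response had 10 of 24 (12 lower adjusted over the list alone, camera adjusted p = 5.20e-07, adjusted p = 0.114 with an estimated correlation, range 3.28e-08 to 0.114). The T cell receptor complex had 5 of 14 (7 lower adjusted over the list alone, camera adjusted p = 0.00207, adjusted p = 0.114 with an estimated correlation, range 0.00111 to 0.114). Receptor complex counts were 3 lower without Th1 WT 2 or Th17 WT 2 or without the shallow libraries. Ribosomal proteins had 2 of 26 higher (1 higher adjusted over the list alone, camera adjusted p = 1.52e-05, adjusted p = 0.362 with an estimated correlation, range 5.24e-07 to 0.362, fry adjusted p = 0.0768). Ribosomal counts were 0 higher without Th1 KO 1, Th17 WT 2, WT 3 or KO 1 or without the shallow libraries, 1 higher without Th1 WT 2, WT 3, KO 2 or Th17 KO 3, 7 higher with limma-voom and 10 higher without Th17 WT 1. Cholesterol synthesis had 5 of 20 lower and 1 higher (1 higher and 7 lower adjusted over the list alone, camera adjusted p = 0.0155, adjusted p = 0.343 with an estimated correlation, range 0.00575 to 0.343, fry adjusted p = 0.0506). Cholesterol synthesis counts were 1 lower without Th1 WT 1, KO 2 or KO 3, 2 lower without Th1 WT 2, WT 3 or Th17 WT 1 or with DESeq2 and 3 lower without Th17 WT 2, WT 3, KO 1, KO 2 or KO 3. For cholesterol synthesis the adjusted p was 0.0504 without Th1 WT 3. Early activation genes had 2 of 19 lower (3 lower adjusted over the list alone, camera adjusted p = 0.0266, adjusted p = 0.362 with an estimated correlation, range 0.00383 to 0.362, fry adjusted p = 0.0938). Early activation counts were 1 lower without the shallow libraries and 4 lower without Th17 KO 3. For early activation the adjusted p was 0.219 without Th17 KO 1 and 0.118 without Th17 WT 3. The Th17 programme had 5 of 21 higher and 3 lower (6 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0306, adjusted p = 0.362 with an estimated correlation, range 0.00502 to 0.362, fry adjusted p = 0.0938). Th17 programme counts were 1 lower without Th1 KO 2. For the Th17 programme the adjusted p was 0.0616 without Th17 KO 1. Cytokines had 2 of 19 higher and 2 lower (4 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.0475, adjusted p = 0.114 with an estimated correlation, range 0.029 to 0.173). Cytokine counts were 1 higher without Th17 WT 1, 4 higher with limma-voom and 1 lower without Th17 WT 1, with limma-voom or without the shallow libraries. For cytokines the adjusted p was 0.149, 0.0716 and 0.0617 without Th17 KO 2, KO 3 and WT 2 and 0.0563, 0.0523 and 0.0599 without Th1 KO 2, WT 2 and WT 3.

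Th17 and Th1 cells of the same genotype differed far more widely than the genotypes. In WT cells, Th17 were lower for 24 of 25 cell cycle genes, a list call kept with an estimated correlation. The Th17 programme was divided, with 13 of 21 genes higher and 5 lower, and its list call was lost with that correlation. Il23r was 0.321 ± 0.0987 CPM in Th1 WT and 41.4 ± 2.63 in Th17 WT (SD, n = 3 per group, log2 fold change 6.98, SE 0.22, adjusted p = 1.52e-18). Ifng was lower in Th17 (-1.99 ± 0.22), as were Gzmb, a granzyme (-4.77 ± 0.30), Il10 (-5.89 ± 0.16) and Fasl (-1.79 ± 0.17), while Tbx21 did not pass (0.26 ± 0.20, adjusted p = 0.349). Of 12189 genes 5738 passed, 2859 higher and 2879 lower in Th17, with 1101 and 444 beyond 2-fold. Il17f had 51 counts in Th17 WT against 1 in Th1 WT, a ratio of 137 (95% counting interval 23.4 to 5500). Il17a had 29 against 0, at least 25.9-fold higher against a floor of 3 counts over the group, but did not pass without Th17 WT 1 (adjusted p = 0.0995, range over all alternatives 6.94e-14 to 0.0995, log2 fold change 4.54 in place of 7.15).

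In WT cells the genes furthest above Th1 in Th17 included Pcsk1, a prohormone convertase, at least 180.0-fold higher, Ntrk3, a neurotrophin receptor, at least 109-fold, Gucy1a1 with a ratio of 497 (95% counting interval 137 to 4120), Tcf7 (7.78 ± 0.23), a factor of naive and memory T cells, and Penk (6.93 ± 0.31), which encodes proenkephalin. Klra5 was lower with a ratio of 126 (95% counting interval 22.4 to 4980), and Ifi214 (-4.87 ± 0.23), Ptger3 (-4.78 ± 0.32), Onecut2 (-4.67 ± 0.55) and Ifi204 (-4.49 ± 0.23) were lower as well. The Th17 programme had 13 of 21 higher and 5 lower (13 higher and 6 lower adjusted over the list alone, camera adjusted p = 0.0123, adjusted p = 0.315 with an estimated correlation, range 0.00545 to 0.315). The follicular helper list had 5 of 7 higher (the same adjusted over the list alone, camera adjusted p = 6.78e-04, adjusted p = 0.1 with an estimated correlation, range 3.13e-04 to 0.1). Examples were Cd200 (5.51 ± 0.17), Bcl6 (2.58 ± 0.23) and Il21 (3.55 ± 0.18). Naive and memory genes had 9 of 15 higher and 4 lower (9 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.019, adjusted p = 0.257 with an estimated correlation, range 0.0106 to 0.257). Examples were S1pr1 (3.55 ± 0.14) and Cd27 (2.02 ± 0.17) and Foxp1 (-1.82 ± 0.11), the last of these lower. The Th1 programme had 5 of 20 higher and 11 lower (5 higher and 11 lower adjusted over the list alone, camera adjusted p = 0.121). Cxcr3, a chemokine receptor of Th1 cells, was higher in Th17 (4.29 ± 0.27) and Ifngr1 (-1.14 ± 0.07) lower.

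Early activation genes were higher in Th17 WT for 12 of 19 and lower for 3 (12 higher and 4 lower adjusted over the list alone, camera adjusted p = 4.65e-04, adjusted p = 0.257 with an estimated correlation, range 1.48e-04 to 0.257). Early activation counts were 0 lower without Th17 WT 1 and 1 lower without Th17 WT 2. Examples were Nr4a1 (3.07 ± 0.25) and Nr4a2 (3.29 ± 0.25). Chemokines and their receptors had 9 of 15 higher and 3 lower (the same adjusted over the list alone, camera adjusted p = 0.00273, adjusted p = 0.134 with an estimated correlation, range 0.00109 to 0.134). Glycolysis genes had 15 of 20 higher (the same adjusted over the list alone, camera adjusted p = 3.25e-04, adjusted p = 0.323 with an estimated correlation, range 4.03e-05 to 0.323). Glycolysis counts were 9 higher without Th17 WT 1. Hypoxia response genes had 8 of 14 (9 higher adjusted over the list alone, camera adjusted p = 0.00243, adjusted p = 0.295 with an estimated correlation, range 2.68e-04 to 0.295). Hypoxia response counts were 4 higher without Th17 WT 1. Cell cycle genes had 24 of 25 lower (the same adjusted over the list alone, camera adjusted p = 2.09e-11, adjusted p = 0.0346 with an estimated correlation, range 5.75e-12 to 0.0346). The unfolded protein response had 15 of 19 lower (16 lower adjusted over the list alone, camera adjusted p = 7.65e-06, adjusted p = 0.0676 with an estimated correlation, range 1.53e-06 to 0.0676). Cholesterol synthesis had 10 of 20 lower and 2 higher (the same adjusted over the list alone, camera adjusted p = 0.00557, adjusted p = 0.295 with an estimated correlation, range 0.00245 to 0.295). Cholesterol synthesis counts were 1 higher without any 1 WT library. The interferon response had 14 of 24 lower and 3 higher (the same adjusted over the list alone, camera adjusted p = 0.00557, adjusted p = 0.315 with an estimated correlation, range 0.00155 to 0.315). Interferon response counts were 8 lower without Th17 WT 1. Ribosomal proteins had 23 of 26 higher (24 higher adjusted over the list alone, camera adjusted p = 2.50e-07, adjusted p = 0.295 with an estimated correlation, range 1.53e-09 to 0.295).

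The other NK receptors had 8 of 13 lower and 1 higher in Th17 WT (2 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.0214, adjusted p = 0.295 with an estimated correlation, range 0.00374 to 0.295). NK receptor counts were 2 higher without Th1 KO 3 or Th17 WT 1 and 5 lower without Th17 WT 1. Examples were Klrc1 (-1.25 ± 0.10) and Klra3 (-1.72 ± 0.25). Costimulation and inhibitory receptors had 9 of 17 higher and 3 lower (the same adjusted over the list alone, camera adjusted p = 0.0246, adjusted p = 0.134 with an estimated correlation, range 0.0182 to 0.134). Mitochondrially encoded genes had 6 of 13 higher (the same adjusted over the list alone, camera adjusted p = 0.00719, adjusted p = 0.389 with an estimated correlation, range 9.88e-04 to 0.389). The regulatory T cell list had 7 of 10 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.0483, adjusted p = 0.323 with an estimated correlation, range 0.0128 to 0.323). Treg programme counts were 4 higher without Th17 WT 1 and 0 lower without Th1 WT 1, Th17 WT 2 or WT 3. For regulatory T cell genes the adjusted p was 0.0568 and 0.113 without Th17 KO 1 and WT 1 and 0.051, 0.0538 and 0.0799 without Th1 KO 1, WT 2 and WT 3. B cell and antigen presentation genes had 5 of 6 higher (6 higher adjusted over the list alone, camera adjusted p = 1.30e-04, adjusted p = 0.0346 with an estimated correlation, range 5.09e-05 to 0.0346). Examples were Cd74 (4.18 ± 0.16) and Ebf1 (6.86 ± 0.41). Cd74 averaged 2.02 ± 0.615 CPM in Th1 WT and 35.4 ± 2.88 in Th17 WT (SD, n = 3), whereas Cd79a had 0 to 3 counts in each of these 6 libraries.

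In KO cells the same comparison gave 6534 genes, 3282 higher and 3252 lower in Th17, with 1147 and 597 beyond 2-fold. Il23r (6.87 ± 0.18) and Lum, a matrix proteoglycan (8.99 ± 0.23), were higher, and Gzmb (-6.30 ± 0.32), Il10 (-7.42 ± 0.17), Fasl (-3.15 ± 0.19), Ifng (-3.43 ± 0.24) and Aqp9 (-5.73 ± 0.17) lower, with n = 3 per group and adjusted p at most 2.65e-06 among these. Il17f had 333 counts in Th17 KO against 2 in Th1 KO, a ratio of 242 (95% counting interval 66.5 to 2010), and Il17a 206 against 0, at least 99.8-fold higher. Of the genes past the threshold in WT, 2423 were also higher and 2429 also lower in KO, against 770 and 768 for independent lists, and 8 passed in opposite directions. Klrk1 was lower in Th17 KO than in Th1 KO (log2 fold change -0.96, SE 0.31, adjusted p = 0.0189), with an adjusted p of 0.133 without Th17 KO 3, 0.0531 without Th1 KO 1 and 0.0696 without Th1 KO 2 (range over all alternatives 7.80e-06 to 0.616), and a log2 fold change of -1.56 without Th17 KO 1 and -0.57 without Th17 KO 3.

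The other NK receptors had 10 of 13 lower and 2 higher in Th17 KO (the same adjusted over the list alone, camera adjusted p = 8.86e-05, adjusted p = 0.101 with an estimated correlation, range 2.61e-05 to 0.101). NK receptor counts were 1 higher without Th1 KO 1 or Th17 KO 3. Examples were Klrd1 (-2.06 ± 0.08), Klrc2 (-2.66 ± 0.12) and Klri2 (-2.78 ± 0.19). Cytotoxic effectors had 11 of 16 lower and 3 higher (the same adjusted over the list alone, camera adjusted p = 0.0137, adjusted p = 0.133 with an estimated correlation, range 0.00896 to 0.133). Cytotoxic counts were 7 lower without Th17 KO 1. The Th1 programme had 12 of 20 lower and 4 higher (the same adjusted over the list alone, camera adjusted p = 0.00344, adjusted p = 0.178 with an estimated correlation, range 0.00168 to 0.178). The Klrk1 neighbours had 14 of 22 lower and 6 higher (6 higher and 15 lower adjusted over the list alone, camera adjusted p = 0.0107, adjusted p = 0.165 with an estimated correlation, range 0.00825 to 0.165). In WT the cytotoxic list (2 of 16 higher and 4 lower, 2 higher and 4 lower adjusted over the list alone) did not pass (camera adjusted p = 0.712, 4 higher without Th1 WT 2 or Th17 WT 1), and the interaction above tests that difference. The Th17 programme had 12 of 21 higher and 6 lower (the same adjusted over the list alone, camera adjusted p = 0.0292, adjusted p = 0.34 with an estimated correlation, range 0.00797 to 0.34). The follicular helper list had 5 of 7 higher and 1 lower (the same adjusted over the list alone, camera adjusted p = 0.00207, adjusted p = 0.131 with an estimated correlation, range 7.50e-04 to 0.131). Naive and memory genes had 10 of 15 higher and 4 lower (the same adjusted over the list alone, camera adjusted p = 0.00858, adjusted p = 0.165 with an estimated correlation, range 0.00476 to 0.165). Glycolysis had 15 of 20 higher and 1 lower (16 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.57e-04, adjusted p = 0.334 with an estimated correlation, range 6.00e-05 to 0.334). Glycolysis counts were 0 lower without Th1 KO 1 or Th17 KO 1. Hypoxia response had 10 of 14 higher (the same adjusted over the list alone, camera adjusted p = 3.12e-04, adjusted p = 0.178 with an estimated correlation, range 6.00e-05 to 0.178). Cell cycle had 24 of 25 lower (the same adjusted over the list alone, camera adjusted p = 1.93e-12, adjusted p = 0.0268 with an estimated correlation, range 9.81e-13 to 0.0268). The unfolded protein response had 17 of 19 lower (the same adjusted over the list alone, camera adjusted p = 1.12e-07, adjusted p = 0.0307 with an estimated correlation, range 3.36e-08 to 0.0307).

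In KO cells early activation had 10 of 19 higher and 1 lower in Th17 (the same adjusted over the list alone, camera adjusted p = 0.00175, adjusted p = 0.211 with an estimated correlation, range 1.62e-04 to 0.211). Early activation counts were 0 lower without Th1 KO 2 or Th17 KO 1 and 4 lower without Th17 KO 3. Chemokines and their receptors had 9 of 15 higher and 3 lower (the same adjusted over the list alone, camera adjusted p = 0.0234, adjusted p = 0.178 with an estimated correlation, range 0.00747 to 0.178). Cholesterol synthesis had 13 of 20 lower and 1 higher (1 higher and 14 lower adjusted over the list alone, camera adjusted p = 1.73e-04, adjusted p = 0.165 with an estimated correlation, range 7.85e-05 to 0.165). Cholesterol synthesis counts were 0 higher without Th1 WT 2, KO 2, KO 3, Th17 KO 1 or KO 3. Ribosomal proteins had 24 of 26 higher (the same adjusted over the list alone, camera adjusted p = 6.11e-09, adjusted p = 0.211 with an estimated correlation, range 1.75e-10 to 0.211). B cell and antigen presentation genes had 6 of 6 higher (the same adjusted over the list alone, camera adjusted p = 5.95e-05, adjusted p = 0.0268 with an estimated correlation, range 2.61e-05 to 0.0268), Cd74 with 4.33 ± 0.14. In the library Th17 KO 3, Igkc had 31, Cd22 16 and Cd79b 15 counts, against 0 to 6 counts of each in the other 5 KO libraries.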

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

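The tests of NK cells, of the shallow libraries and of the sort were chosen only after the results they bear on were seen; the splits of the samples were planned.

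The genotype difference differed between Th17 and Th1 cells for single genes, by the interaction test. Values are the log2 genotype difference in Th17 minus that in Th1. More negative in Th17 were Klrd1 (-1.76), Serpine2 (-1.49), Klri2 (-2.26), Klrc2 (-1.57), Klrc1 (-1.43), Ifngr1 (-0.47), Lag3 (-0.82), Cd96 (-1.28), Tmem176b (-1.23), Fasl (-1.36), Aqp9 (-1.95), Trp73 (-2.09), Rbm47 (-1.91) and Mecom (-2.12). More positive were Tspan32 (2.90), Gbp2 (0.68), Cysltr2 (0.71), Cd274 (0.74), Casp1 (0.62), Ppp2r3c (0.73), Iigp1 (0.92) and Tcf4 (0.94). Klrc1, Ifngr1, Lag3, Cd96, Tmem176b and Fasl are members named in the genotype comparisons and tested here as such. Of these 6 members Klrc1 passed with each library left out, while the adjusted p of the other 5 rose above 0.05. Ifngr1 had 0.0546 to 0.103 without Th1 WT 3, KO 1, KO 2, Th17 WT 1 or KO 3 (range 3.43e-05 to 0.103), Lag3 0.0594 to 0.172 without Th1 WT 1, WT 3, KO 1, KO 2, Th17 WT 1, WT 2, WT 3, KO 2 or KO 3 (range 4.07e-04 to 0.836), Cd96 0.052 to 0.101 without Th1 WT 1, WT 3, KO 1, KO 3, Th17 WT 3, KO 1 or KO 2 (range 1.48e-08 to 0.397), Tmem176b 0.0538 to 0.123 without Th1 WT 1, WT 3, KO 2, Th17 WT 2, WT 3, KO 1, KO 2 or KO 3 (range 2.02e-04 to 0.349) and Fasl 0.0619 to 0.421 without Th1 WT 1, WT 2, WT 3, KO 1, KO 3, Th17 WT 1, KO 2 or KO 3 (range 7.53e-11 to 0.421), the last with a value of -0.69 without Th17 WT 1. Of the other 16 genes 8 had an adjusted p above 0.05 when 1 library was left out. Tcf4 had 0.0652, 0.0565, 0.173 and 0.0641 without Th17 KO 1, KO 3, WT 1 and WT 2 and 0.0726, 0.0916, 0.0744, 0.0587 and 0.051 without Th1 KO 1, KO 2, WT 1, WT 2 and WT 3 (range over all alternatives 6.08e-04 to 0.342). Iigp1 had 0.182 without Th17 KO 3 and 0.124 without Th17 WT 1 (range 1.04e-06 to 0.182), Ppp2r3c 0.0664 without Th17 WT 1 (range 0.0015 to 0.726), Casp1 0.074 without Th17 KO 3 (range 9.60e-04 to 0.644), Trp73 0.137 without Th17 WT 1 (range 8.13e-06 to 0.137), Aqp9 0.197 without Th17 WT 1 (range 1.79e-05 to 0.197) and Rbm47 0.0501 without Th17 KO 3 (range 2.11e-04 to 0.0541). Mecom had 0.154 without Th17 KO 3 and 0.135 without Th17 WT 1 (range 4.78e-04 to 0.501), and a value of -3.19 without Th17 KO 1.

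Lists differed likewise, with mean differences of -1.149 for other NK receptors, -0.4682 for the Th1 programme, -0.786 for cytotoxic effectors and -0.9772 for Klrk1 and its chromosome 6 neighbours, which hold many of the NK receptors. For the count of interaction genes the splits cannot decide on chance: 8 of 100 drawn splits within each cell type, the real one included, gave 72 or more genes, and the highest of the others gave 151. The test is limited, since splits can turn average differences into interaction: 1 gave 137 average and 27 interaction genes, another 27 and 137.

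The pattern weighed is the lower level of 23 NK receptor, cytotoxic and Th1 genes in Th17 KO, chosen for passing there, which favours passing in refits. NK cells in the WT sort are argued against, since Tyrobp and Fcer1g together had 5 counts in Th17 WT, with an upper limit of 11.7 counts or 0.763 CPM, against a Klrd1 difference of 62.7 CPM. The 3 shallow libraries as the whole cause are argued against too, for these genes: with a term for them the median moved from -1.62 (quartiles -1.86 and -0.90) to -1.54 (-1.84 and -0.77), and 20 of the 23 stayed past the threshold. Without them all 23 were lower (median -1.47), but that fit has 1 Th17 WT library and is given as a value only. Leaving out the dominant ID kept 22, and thinning kept 17 of 20 with a value. Whether WT cells were higher because of the NKG2D gate, which may select cells rich in NK receptors, or because KO cells lacked the receptor cannot be told apart, since 0 of the WT libraries analysed here came from cells without the gate.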

How the results depend on the processing

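The 3 alternatives for the shallow libraries were chosen after seeing the data; all others were planned. No reported direction reversed in any of them, where a gene past the threshold in neither fit counts as unchanged. With RLE size factors all 417 named-gene results and all 74 list calls kept their side of the threshold. In the Th1 genotype comparison (562 genes) DESeq2 gave 306, limma-voom 1074, thinned libraries 177 and a fit of the 2 groups alone 922. In Th17 (711 genes) limma-voom gave 463, thinned libraries 328, the 2 groups alone 356 and the fit without the 3 shallow libraries, which has 1 Th17 WT library, 319. Thinned libraries gave 3296 genes for Th17 with Th1 in WT, 3561 in KO, 509 for the average and 39 for the interaction, and fewer genes were tested there (9564). With no filter the interaction had 207 genes. For the other changes the cause was not tested. With an estimated correlation the lists past the threshold numbered 0 of 9 in Th1, 4 of 9 in Th17, 2 of 17 and 3 of 16 for polarization in WT and KO, 5 of 13 for the average and 4 of 10 for the interaction.

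Leaving out 1 library gave 260 to 679 genes in Th1, 411 to 713 in Th17, 4197 to 5892 and 5551 to 6683 for polarization in WT and KO, 935 to 1215 for the average and 38 to 108 for the interaction. List counts ranged from 6 to 13, 9 to 11, 16 to 17, 16 to 18, 11 to 14 and 7 to 11 in that order. The libraries behind the lowest Th1, Th17 and interaction counts are named above. Over named genes, left-out libraries ended 239 calls and made 16, DESeq2 ended 30 and made 2, limma-voom ended 17 and made 5, thinning ended 62 and made 1, the fit without the shallow libraries ended 42 and made 5, the term for them ended 13 and made 3, no filter ended 5 and made 6, the 2 groups alone ended 22 and made 6, and leaving out the dominant ID ended 1. Of the list calls, fry ended 10, left-out libraries 40, the fit without the shallow libraries 15, the term 8 and the dominant ID 1. Of 136 list counts with at least 2 members past the threshold, 62 moved by over 1.5 times with thinning, 27 without the shallow libraries, 19 with DESeq2, 13 with no filter, 11 with limma-voom, 6 with the term, 1 without the dominant ID and 0 with RLE, and 13 of 109 with the 2 groups alone. No value was had for 3 named-gene results with DESeq2, 15 with the 2 groups alone and 45 with thinned libraries. The share of higher genes moved from 36.7% to 24.3% in Th1 with thinned libraries, from 31.1% to 19.5% with DESeq2 and 18.5% without the shallow libraries in Th17, and from 19.4% to 29.5% with no filter, 31.6% with the block and 33.3% without Th17 WT 1 in the interaction, against 12% without the shallow libraries and 14.7% with DESeq2.

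Library codes in the titles hint at pairs of WT and KO samples, which the labels do not state. With a replicate block by these codes 1315 genes passed in Th1, 1117 in Th17 and 329 in the interaction, it made 14 named-gene calls and ended 0 of 182, moved 19 of 51 list counts by over 1.5 times, and it was not run for polarization. In Th1 the calls made included Ifng (adjusted p = 0.00934) and Tbx21 (adjusted p = 2.85e-06), with ranges given above. Deviations of same-numbered samples over 8043 genes correlated at 0.33, 0.12 and 0.34 in Th1, each sample best with its own number, and at 0.44, 0.18 and -0.14 in Th17, where Th17 WT 3 correlated best with Th17 KO 2 (0.24), a hint from the data and not the design. Depth limits the Th17 groups most, since a count of 0 in the smallest library, Th17 WT 3, allows up to 1.82 CPM of its total counts. On the TMM-normalised scale that floor is higher, since the TMM factor of this library was 0.585.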

Other observations

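The tests on the chromosome 7 genes were chosen only after the calls were seen; the test of ribosomal RNA and the splits of the samples were planned.

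Some listed genes outside the lineage programmes differed between Th17 and Th1. Of 7 tested Th2 genes 4 were higher and 2 lower in Th17 WT (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.147) and 4 higher and 2 lower in Th17 KO (4 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.241). Gata3, the Th2 transcription factor, was higher (1.32 ± 0.16 in WT and 1.24 ± 0.15 in KO, log2 fold change ± SE, n = 3 per group), as was the chemokine receptor Ccr8 (4.82 ± 0.49 and 4.01 ± 0.50), while Ptgdr2, a prostaglandin receptor, was lower (-3.91 ± 0.48 and -4.31 ± 0.41). Il13 was at least 11.6-fold higher in WT and 22.8-fold in KO. Oxidative phosphorylation genes had 4 higher and 8 lower of 24 in WT (4 higher and 8 lower adjusted over the list alone, camera adjusted p = 0.121, 2 higher without Th1 WT 1, WT 3 or Th17 WT 1 and 5 lower without Th17 WT 2), with Cox5a (-0.58 ± 0.08) and Sdhb (-0.45 ± 0.07) lower. Heat shock genes had 1 higher and 5 lower of 10 (3 higher and 5 lower adjusted over the list alone, camera adjusted p = 0.326, 2 higher without Th17 WT 1, WT 2, KO 1 or KO 2), with Hsp90aa1 (-0.39 ± 0.06) and Dnajb1 (-0.44 ± 0.08) lower. Neighbours of Thy1 on chromosome 9, where the congenic allele lies, had 3 higher and 0 lower of 33 in Th1 KO (3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.087, 0 higher with DESeq2 and 1 higher without Th1 WT 3, KO 1 or KO 3) and 0 higher and 1 lower in Th17 KO (0 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.668, 0 lower without Th1 WT 2, Th17 WT 2, WT 3 or KO 3 and 2 lower without Th17 KO 2). Of 4 tested myeloid genes 2 were higher and 1 lower in Th17 WT than in Th1 WT (2 higher and 1 lower adjusted over the list alone, 0 higher without Th1 WT 2 or Th17 WT 1, 1 higher without Th1 WT 3, Th17 WT 2 or WT 3 and 0 lower without Th17 WT 1), and 0 were higher and 1 lower in KO (0 higher and 1 lower adjusted over the list alone). In WT the higher genes were Cd14 and Itgam. Both calls were lost with DESeq2 (adjusted p = 0.0649 and 0.11), with ranges over all alternatives of 0.00111 to 0.169 and 0.0057 to 0.133. The 1 tested CD8 T cell gene, Cd8b1, was higher in Th17 KO (1.09 ± 0.25, 1 higher adjusted over the list alone), a call lost with thinned libraries (adjusted p = 0.096, range over all alternatives 1.13e-04 to 0.096). For the erythroid list 0 of 7 genes had enough counts for a test.

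Genotype calls of the average comparison gathered on distal chromosome 7, where the fullest window of 30 tested genes (133709333 to 140822178 on GRCm38) held 15 calls, 7 higher and 8 lower in KO, against 2.97 expected. Echs1 was higher (1.07 ± 0.10 in Th1 and 1.12 ± 0.13 in Th17) and Zfp941 lower (-2.99 ± 0.34 and -3.43 ± 0.33). The next fullest window, on chromosome 6 (127446840 to 131353597), holds Klrk1 and had 13 calls, above the 95th percentile of 11 for the fullest window of shuffled calls. A segment of another strain origin in 1 of the mouse lines may account for this, but it stays open: 1 of 1000 shuffles of the calls reached 15 (permutation p = 0.002), while equally many polarization genes of smallest p (1194 each) had windows of up to 12 in WT and 14 in KO, the latter also on chromosome 6 (128357000 to 134438736). Tnfrsf22, Tnfrsf23 and Tnfrsf26 lie outside the chromosome 7 window, so their summed CPM, with a KO over WT ratio of 0.168 in Th1 and 0.0853 in Th17, says nothing of its calls. Whether such a segment reaches them was not tested.

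The 3 shallow Th17 libraries shared further features. Of the counts other than the dominant ID, Lars2 had 182 to 1081 CPM, Gm42418 2437 to 9025 and Gm26917 2883 to 4929, against at most 136, 1880 and 2280 in the other 9 libraries. Ribosomal RNA carried into these libraries could account for this, and its 353 genes took a median of 0.000672% of their counts (0.000468 to 0.000948) against 0.000380% (0.000298 to 0.000429) in the other 9. These shares rest on 15, 4 and 8 counts, too few to decide, and miss ribosomal RNA counted under other IDs. The requirement on counts was added after the shares were seen.

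Splits of 6 samples into 3 and 3 number 10, too few for a share under 0.05, and only the real one gave as many genes in each comparison. The real and the highest other counts were 562 and 0 in Th1, 711 and 68 in Th17, 5738 and 0 for polarization in WT and 6534 and 0 in KO. For the average, only the real one of 100 drawn splits gave 1198 genes (highest other 360), so chance among samples is unlikely.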
